A study of Homo sapiens with 8 samples.

How the data were processed

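The series holds 8 single-colour Affymetrix 3' expression arrays of human lung cancer cells: 2 of parental PC9, 3 of PFR3 grown without drug and 3 of PFR3 grown in PF299804. Per the labels' protocols, cells grew exponentially in RPMI with 10% fetal bovine serum, RNA was isolated with Trizol and an RNeasy clean-up, and biotin-labelled cRNA was made from an oligo-dT primed first strand, so signal depends on the 3' end of a transcript. Samples were grouped by the labels' cell names and drug response.

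The deposited values are RMA intensities per probe set, per the submitters' processing notes; the RMA version and its settings are not given in the sources used here. As a method RMA corrects background, quantile-normalises between arrays and summarises the probes of a probe set, so a change of total RNA per cell cannot be seen in these values. The intensities were deposited on a linear scale, with array minima near 15, and were taken to log2 here. No sample's scanner file was used here.

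The table held 22277 probe sets. Of these, 62 were controls, 19064 had 1 gene symbol, 1043 had several and 2108 had none in GEO's platform annotation. No name was taken from a probe set with several symbols. Updating symbols through Entrez identifiers changed 0 of them. Each gene was represented by the probe set with the highest mean over all 8 arrays, which left 11963 genes. Of the genes with more than 1 probe set, 1, 108 and 14 had probe sets called in opposite directions in the 3 comparisons in the order of the report. The 3' minus 5' differences of the beta-actin and GAPDH control probe sets served as the measure of RNA degradation. For arrays the number of samples limits the precision, and the bacterial control probe sets had an upper decile of 5.16 to 5.55 log2 units, taken as background. Where arrays of a group were not above it, a change given as "at least" sets the other group's mean against, per array, the higher of that level and the gene's own value; this was added after the data were seen.

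Comparisons were made with limma 3.58.1 in R 4.3.3. All 8 arrays entered 1 fit of group means, with eBayes without a trend and 5 residual degrees of freedom (prior degrees of freedom 3.57). The fit assumes the same spread in each group. The median deviation from the group mean was 0.20 log2 units on the parental arrays and 0.04 to 0.09 on the others. Adjusted p against parental cells may therefore be too small, and those between the resistant cultures too large. A gene was called at an adjusted p (Benjamini-Hochberg over the 11963 genes) under 0.05. The comparison of the resistant cultures is also the test of whether their differences from parental cells differ. Fold changes are differences of group means on the log2 scale, with limma's standard error. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 37 lists per comparison. Camera compares a list with the other genes; with an estimated correlation it called 0 lists in each comparison, and the smallest adjusted p were 0.0635, 0.142 and 0.075. The lists, written from general knowledge of pathways and cell types, name 689 genes, of which 598 were measured. The design of the fit, the lists, the alternatives and the rule for named genes were fixed before the data were examined.

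Genes named in the text follow that rule: in each comparison the 12 with the largest positive and the 12 with the largest negative log2 fold change among called genes whose arrays do not overlap between the groups, all measured members of the ERBB and IGF lists, and up to 4 called members of each called list with the largest absolute change. Further list members, such as those that moved against their list, were named after their values were seen.

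Alternatives tried were an intensity trend in eBayes, only genes above the median brightness, the mean of a gene's probe sets, every probe set on its own, cyclic loess or median centring on top of the deposited values, array weights, only the 2 groups compared, the replicate number as a block, a minimum change of 1 log2 unit, camera with an estimated correlation, fry, and each array left out in turn. Leaving out parental replicate 2 together with on-drug replicate 3 was added after the data were seen. When 1 parental array was left out, the remaining one was assumed to vary like the arrays of the other groups. A sign change under an alternative was counted as reversed only where the gene was called in at least 1 of the fits; 68 other sign changes concerned values called in neither.

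The calls were tested on simulated data with 11963 genes and known folds. For drug-free against parental cells the procedure recovered 14.9% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 86.4% of those changed 4-fold, with 2 false calls. For on-drug against parental cells these shares were 31.3%, 67.2% and 90.9%, with 12 false calls, and between the resistant cultures 32.8%, 80.6% and 90.9%, with 8 false calls. Both comparisons against parental cells had the same simulated design and spread, and each was simulated only once. The gap between their shares thus comes from the genes and noise drawn, not from a difference in sensitivity. Raising the ERK pathway output list by 0.5 log2 units gave camera adjusted p = 8.37e-26 with 0 of the 36 other lists called. In these simulations noise was independent between genes and had the same spread in all groups. They do not cover the wider spread of the parental pair or noise shared across an array, so real error rates may be higher. The order of genes along chromosomes came from RefSeq annotation of the assembly GRCh38.p14 and was used for neighbourhood alone; the array's own build is not given in the sources used here. Of the 11963 genes, 11954 had a place in it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.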

Results

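Gene expression was measured in PC9, a human non-small cell lung cancer line that carries an activating EGFR deletion, and in PFR3, cells resistant to PF299804 (dacomitinib). PF299804 is an irreversible inhibitor of the ERBB family of receptor tyrosine kinases. Each of the 8 samples was hybridised to 1 single-colour Affymetrix array. The parental PC9 cells, sensitive to the drug, had 2 arrays. PFR3 cells grown without drug had 3 arrays, and PFR3 cells kept in PF299804 had 3 arrays. The study's title names resistance to irreversible EGFR inhibitors and the IGF1R pathway, so the comparisons ask what differs between sensitive and resistant cells and what the drug's presence adds. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

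Median intensity lay between 154 and 161 on the 8 arrays. Across 11963 genes, the drug-free PFR3 arrays correlated with each other at 0.997 to 0.998. On-drug replicates 1 and 2 correlated at 0.998, and on-drug replicate 3 at 0.990 and 0.992 with them. The parental pair was further apart, with a correlation of 0.949 and 1335 genes differing by more than 1 log2 unit. Parental replicate 1 correlated with the drug-free arrays at 0.981 to 0.983. The difference between the 3' and the 5' control probe sets of beta-actin (ACTB), a sign of RNA degradation, was -0.04 and -0.06 on the parental arrays and -0.09 to -0.04 on the drug-free arrays. It was 0.22, 0.19 and 1.16 log2 units on on-drug replicates 1, 2 and 3. For GAPDH the on-drug values were 0.03, 0.17 and 0.54, and those of the other 5 arrays lay between -0.15 and -0.09. The median log2 fold change of all genes was -0.13 for drug-free against parental cells, -0.11 for on-drug against parental cells and -0.01 between the resistant cultures. After cyclic loess these medians were -0.02, -0.00162 and 0.01. The medians against parental cells, drug-free and on drug, were -0.25 and -0.22 without parental replicate 1 and -0.014 and -0.024 without replicate 2. Among genes above the median brightness they were -0.0099 and 0.05. The shift of about -0.1 over all genes thus depends on the parental array and on brightness. Changes against parental cells are to be read with it in mind, but it does not hold for bright genes. The upper decile of the bacterial control probe sets on each array, 5.16 to 5.55 log2 units, was taken as background. In the order of the report's comparisons, 30, 105 and 33 called genes had 1 group with no array above it, so that their change is only bounded, and 10, 51 and 12 had both groups there.

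**Figure D1:**
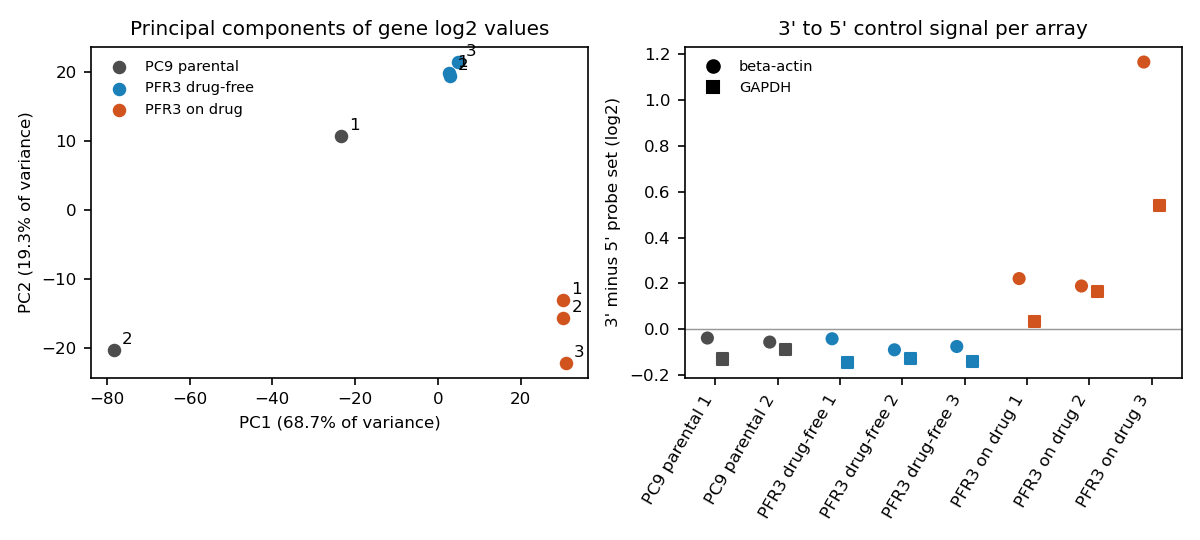
Left, the 8 arrays on principal components 1 and 2 of log2 intensity over 11963 genes (68.7% and 19.3% of the variance), 1 point per array; right, the 3' minus 5' log2 difference of the ACTB and GAPDH control probe sets, 1 point per array. Parental replicates 1 and 2 lie at -23.4 and -78.3 on component 1, and on-drug replicate 3 has the highest ACTB difference, 1.16.

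In drug-free PFR3 cells 10 of 18 squamous and basal genes and 10 of 21 NF-kB and inflammatory genes fell against parental PC9 cells, while 10 of 16 cholesterol and 4 of 9 fatty acid synthesis genes rose. Camera called these 4 lists with its preset correlation and lost them otherwise (adjusted p = 0.354, 0.288, 0.0635 and 0.288 with an estimated correlation). S100A8, a calcium-binding protein of inflamed epithelium, fell 88.7-fold, from 12.63 ± 0.43 (SD, n = 2) to 6.16 ± 0.29 log2 units (n = 3), with a log2 fold change of -6.47 (SE 0.23, adjusted p = 4.93e-06). KRT5, the basal cell keratin, fell 26.8-fold, from 12.23 ± 0.34 to 7.48 ± 0.13 (log2 fold change -4.74, SE 0.18, adjusted p = 5.41e-06). SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose 6.64-fold, from 9.21 ± 0.48 to 11.94 ± 0.05 (log2 fold change 2.73, SE 0.18, adjusted p = 0.000136). In all, limma called 1084 genes higher and 1013 lower. A fit of only these groups, which does not use the narrower spread of the on-drug arrays, called 172 and 221.

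After SCD, the genes that rose most were SLC7A11, the cystine transporter (2.64), CALD1, caldesmon (2.57), DCPH1 (2.54), ANKRD28 (2.50), BLTP1 (2.49) and ACKR3, a scavenger receptor of CXCL12 (2.42). Next came CAPN7 (2.39), the lipid kinase PIK3C2A (2.39), NUCB2 (2.25), dystrophin (DMD, 2.24) and osteopontin (SPP1, 2.22). These 12 genes had a median of -1.79 on parental replicate 2 relative to replicate 1, and 11 of the 12 were lower there, against a median of 0.23 over all genes. CAPN7 and ANKRD28 lie in a run of 25 neighbouring expressed genes, VGLL4 to TOP2B, with a median log2 difference of 0.98 between drug-free PFR3 and parental replicate 1. PIK3C2A and NUCB2 lie in another such run, DENND2B to NUCB2, with a median of 0.50. After S100A8 and KRT5, the genes that fell most were SPRR1B, a protein of the cornified envelope (-4.09), the protease inhibitor elafin (PI3, -3.96), OLFML3 (-3.89), KRT13 (-3.73), KRT23 (-3.46) and RARRES1 (-3.16). They were followed by IL1RL1, the receptor of IL-33 (-3.14), LY6D (-3.11), the siderophore-binding lipocalin LCN2 (-2.90) and CRIP1 (-2.71). For DCPH1, BLTP1 and DMD 1 of the 2 parental arrays was not above background. Adjusted p lay between 4.93e-06 and 0.0261 for these 24 genes. Of them, SLC7A11, CALD1, DCPH1, BLTP1 and DMD lost the call without any 1 of the drug-free arrays and PIK3C2A without drug-free replicate 2 or 3, with adjusted p up to 0.0854; DMD also lost it without on-drug replicate 2 (0.0516). The remaining 18 kept it without any 1 array. Without parental replicate 2 the rises of SLC7A11 (1.27), CALD1 (1.42), DCPH1 (1.33), BLTP1 (1.19), PIK3C2A (1.36) and DMD (1.06) were smaller by more than 1.5 times. Without replicate 1 that of SLC7A11 (4.01) was larger by as much. The fitted 3.78 of BLTP1 and 3.43 of DMD then rest on replicate 2, where neither gene was above background, and are not read as larger rises.

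In the cholesterol synthesis and uptake list 10 of 16 measured members rose and 0 fell, and 11 rose and 0 fell when adjusted over the list alone (camera adjusted p = 7.97e-09; adjusted p = 0.0635 with an estimated correlation). MSMO1, a sterol oxidase, rose by 2.16, INSIG1, the sterol-regulated retention protein of the endoplasmic reticulum, by 1.99, HMGCS1, the HMG-CoA synthase, by 1.87 and IDI1, the isopentenyl diphosphate isomerase, by 1.69. In the fatty acid synthesis list 4 of 9 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.000899; adjusted p = 0.288 with an estimated correlation). They were SCD, the elongase ELOVL5 (1.40), the malic enzyme ME1 (0.98) and the acetyl-CoA carboxylase ACACA (0.89). The median of the cholesterol list was 0.31 higher on parental replicate 2 than on replicate 1, and that of the fatty acid list stood at -0.68. MSMO1, ELOVL5, ME1 and ACACA each lost the call without any 1 of the drug-free arrays, with adjusted p up to 0.107 for ACACA, which also lost it without on-drug replicate 1, 2 or 3 (0.0617, 0.0631 and 0.0587). Without parental replicate 2 the rises were 1.22 for MSMO1, 1.14 for HMGCS1, 0.78 for ELOVL5, 0.58 for ME1 and 0.42 for ACACA, and without replicate 1 that of ACACA was 1.35. With the mean of a gene's probe sets ELOVL5 stood at 0.30 and was not called.

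In the NRF2 and oxidative stress list 8 of 17 rose and 0 fell, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.94e-06; adjusted p = 0.0635 with an estimated correlation). SLC7A11 rose by 2.64, the aldehyde dehydrogenase ALDH3A1 by 1.63, the haem oxygenase HMOX1 by 1.39 and the efflux pump ABCC2 by 1.34. The aldehyde dehydrogenase and cytochrome P450 list had 4 of 12 members that rose and 0 that fell, also when adjusted over the list alone (camera adjusted p = 0.0364; adjusted p = 0.296 with an estimated correlation). These were CYP4F3 (1.65), ALDH3A1, CYP1B1 (1.45) and ALDH2 (1.02), while the median of the list was 0.07 and its mean 0.46. Its adjusted p was 0.212 without parental replicate 1 and 0.117 among genes above the median brightness, in a range of 0.00166 to 0.296 over all alternatives. On parental replicate 2 the medians of the NRF2 and the aldehyde dehydrogenase lists were 0.10 and 0.15 higher than on replicate 1. SLC7A11 and HMOX1 lost the call without any 1 of the drug-free arrays (adjusted p up to 0.0862), and CYP1B1 without parental replicate 2 (0.0736), any drug-free array (0.0766 to 0.0916) or on-drug replicate 2 (0.0514). SLC7A11 rose by 4.01 without parental replicate 1 and 1.27 without replicate 2, HMOX1 by 0.81 without replicate 1 and CYP1B1 by 0.82 without replicate 2.

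In the squamous and basal list 0 of 18 rose and 10 fell, and 11 fell when adjusted over the list alone (camera adjusted p = 3.54e-08; adjusted p = 0.354 with an estimated correlation), with KRT5, SPRR1B, PI3 and KRT13 in front. The NF-kB and inflammatory list had 0 of 21 that rose and 10 that fell, and 13 fell when adjusted over the list alone (camera adjusted p = 6.68e-06; adjusted p = 0.288 with an estimated correlation). Examples were LCN2, the neutrophil chemokine CXCL8 (-2.58, with 1 of the 3 drug-free arrays not above background), the deubiquitinase TNFAIP3 (-1.69) and the NF-kB inhibitor NFKBIA (-1.33). In the antigen presentation list 0 of 19 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.00088; adjusted p = 0.564 with an estimated correlation). Examples were the immunoproteasome subunits PSMB9 (-1.27) and PSMB8 (-0.98), the peptide transporter TAP2 (-0.90) and HLA-B (-0.87). PSMB8 lost the call without drug-free replicate 2 or 3 (0.0663 and 0.063). On parental replicate 2 the medians of these 3 lists were 0.39, 0.23 and 0.47 higher than on replicate 1.

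ERK pathway output genes, the immediate targets and feedback regulators of the kinase ERK, fell in part: 1 of 18 rose and 6 fell, or 2 and 9 when adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.532 with an estimated correlation). The AP-1 factor FOSL1 (-2.07), the small MAF protein MAFF (-1.66), MYC (-0.91) and PHLDA1 (-0.88) fell, while SPRY1, an inhibitor of receptor signalling, rose by 0.50. The list's adjusted p was 0.108 without parental replicate 1, in a range of 0.00236 to 0.532 over all alternatives, and its median was 0.32 higher on parental replicate 2 than on replicate 1. Mitotic genes went both ways: 6 of 25 rose and 3 fell, or 13 and 5 when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.01; adjusted p = 0.564 with an estimated correlation). The kinetochore protein CENPF rose by 1.39, the topoisomerase TOP2A by 1.26 and the checkpoint kinase BUB1 by 1.17, while the mitotic kinase PLK1 fell by 1.03. On parental replicate 2 the median of the mitotic genes was -0.80 relative to replicate 1, with 18 of 25 lower. The mitotic list was not called without parental replicate 2 (adjusted p = 0.3), after cyclic loess (0.177), among genes above the median brightness (0.23) or by fry (0.168), in a range of 0.000207 to 0.564 over all alternatives. TOP2A and BUB1 lost the call without any 1 of the drug-free or on-drug arrays (adjusted p 0.0749 to 0.134). Their rises were 2.05 and 1.92 without parental replicate 1, and 0.48 and 0.42 without replicate 2. With the mean of a gene's probe sets PHLDA1 stood at -0.19 and BUB1 at 0.46, and neither was called.

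With an estimated correlation camera called 0 of the 37 lists in this comparison, 5 had an unadjusted p under 0.05, and limma's fry, which asks whether a list's genes move 1 way on balance, called 23. The number of genes called was 2097 with all arrays, 7966 without parental replicate 1, 684, 571 and 515 without drug-free replicate 1, 2 and 3, and 1291 and 1159 without on-drug replicate 1 and 2.

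PFR3 cells kept in PF299804 differed from parental cells in more genes: limma called 2253 higher and 2489 lower. With only these groups in the fit, 1387 and 1104 were called. KRT13, a keratin of stratified epithelium, fell at least 46.4-fold, from 10.78 ± 0.20 (SD, n = 2) to 5.14 ± 0.24 log2 units (n = 3, with 2 of these arrays not above background; fitted log2 fold change -5.65, SE 0.16, adjusted p = 1.85e-06). S100A8 fell by 5.32 (SE 0.23, adjusted p = 3.92e-06) and KRT5 fell by 4.90 (SE 0.18, adjusted p = 3.19e-06). FOSL1 fell from 11.19 ± 0.32 to 7.28 ± 0.11 (log2 fold change -3.90, SE 0.16, adjusted p = 3.92e-06). OLR1, the receptor of oxidised low-density lipoprotein, was not above background on either parental array and rose at least 12.1-fold, to 9.01 ± 0.17 (log2 fold change of at least 3.6, adjusted p = 3.19e-06).

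CALD1 rose by 4.31 (SE 0.52, adjusted p = 0.000563), with an SD of 1.62 in its parental arrays. The other genes of the 12 with the largest fitted rise, besides OLR1, were ACKR3 (4.17), the mannosidase MAN1A1 (3.58), ARID5B (3.44), STXBP6 (3.42), the sulphate transporter SLC26A2 (3.36), TBC1D9 (3.33), VPS13C (3.32), the alpha-tubulin TUBA1A (3.29), the growth factor PDGFD (3.28) and RASGRP1, an activator of RAS (at least 2.59). RASGRP1 was not above background on either parental array, and TBC1D9 and VPS13C were not on 1 of them. These 12 genes had a median of -1.15 on parental replicate 2 relative to replicate 1, with 9 lower, and a median of -0.28 on on-drug replicate 3 relative to the mean of the other on-drug arrays. The remaining genes that fell most were IL1RL1 (-4.30), the chloride channel ANO1 (-3.99), SPRR1B (-3.95), S100A9, the partner of S100A8 (-3.75), KRT23 (-3.54), OLFML3 (-3.50), the cytolinker PLEC (-3.41) and MAFF (-3.33). All 24 kept the call without any 1 array, and their adjusted p lay between 1.85e-06 and 0.0139.

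ERK pathway output genes fell in nearly the whole list: 0 of 18 rose and 16 fell, 17 when adjusted over the list alone, with a median of -1.56 (camera adjusted p = 1.48e-09; adjusted p = 0.144 with an estimated correlation). FOSL1 and MAFF led, followed by the ERK phosphatase DUSP6 (-2.37) and PHLDA1 (-2.29). The cholesterol synthesis and uptake list had 12 of 16 that rose and 0 that fell, also when adjusted over the list alone (camera adjusted p = 1.54e-06; adjusted p = 0.142 with an estimated correlation). MSMO1 rose by 3.19, HMGCS1 by 3.0, INSIG1 by 2.69 and SC5D, the sterol desaturase, by 2.67. In the fatty acid synthesis list 4 of 9 rose and 0 fell, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.402 with an estimated correlation). They were SCD (2.86), ELOVL5 (1.90), ME1 (1.56) and ACACA (1.0). The fatty acid list's adjusted p was 0.0574 without on-drug replicate 1, 0.0953 after cyclic loess and 0.173 among genes above the median brightness, in a range of 0.00173 to 0.402 over all alternatives. In the NRF2 and oxidative stress list 11 of 17 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 3e-04; adjusted p = 0.142 with an estimated correlation). SLC7A11 rose by 2.73, HMOX1 by 2.31, ME1 by 1.56 and TXNRD1, a thioredoxin reductase, by 1.12, while OSGIN1 fell by 0.42. Without parental replicate 1 the rises of SLC7A11 and TXNRD1 were 4.10 and 1.71, and without replicate 2 they were 1.36 and 0.52, with 0.54 for ACACA.

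In the squamous and basal list 1 of 18 rose and 11 fell, or 1 and 12 when adjusted over the list alone (camera adjusted p = 5.47e-05; adjusted p = 0.488 with an estimated correlation). KRT13, KRT5, SPRR1B and PI3 (-2.54) fell, and KRT16, a keratin of activated keratinocytes, rose by 1.69. The NF-kB and inflammatory list had 0 of 21 that rose and 10 that fell, also when adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.427 with an estimated correlation). LCN2 (-3.21), CXCL8 (-2.54, with 1 of the 3 on-drug arrays not above background), TNFAIP3 (-2.37) and the cytokine LIF (-1.5) fell most. In the lung alveolar and secretory list 1 of 15 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.00921; adjusted p = 0.488 with an estimated correlation). The secreted mucin MUC5B (-2.17), the adhesion proteins CEACAM5 (-1.54) and CEACAM6 (-1.48) and the mucin MUC5AC (-0.75) fell, while the membrane mucin MUC1 rose by 0.60. DNA replication genes fell in most of the list: 14 of 24 fell and 3 rose, or 15 and 3 when adjusted over the list alone (camera adjusted p = 0.00894; adjusted p = 0.329 with an estimated correlation). The licensing factor CDT1 (-1.80), the ribonucleotide reductase subunit RRM2 (-1.5), the cyclin CCNE1 (-1.33) and the helicase subunit MCM5 (-1.32) fell most. CCNE2 (1.27), RRM1 (1.38) and CDC45 (0.47) rose, RRM1 by 0.74 without parental replicate 2. The DNA replication list's adjusted p was 0.182 without parental replicate 1, in a range of 0.000112 to 0.329 over all alternatives.

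Medians on on-drug replicate 3 relative to the other on-drug arrays were -0.06 for the ERK list, -0.12 for cholesterol, -0.11 for fatty acid, 0.18 for squamous, 0.07 for NF-kB, 0.13 for lung and 0.04 for DNA replication genes, with 0.03 over all genes. With an estimated correlation camera called 0 of the 37 lists, 4 had an unadjusted p under 0.05, and fry called 25. The number of genes called was 4742 with all arrays and 8374 without parental replicate 1, while the number lower fell from 2489 to 1649 and 1638 without on-drug replicate 1 and 2.

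Between the resistant cultures, 15 of 18 ERK pathway output genes and 12 of 24 DNA replication genes fell on drug (adjusted p = 0.075 and 0.075 with an estimated correlation). FN1, the matrix protein fibronectin, rose 10.3-fold on drug, from 9.11 ± 0.09 to 12.47 ± 0.02 log2 units (SD, n = 3 and 3; log2 fold change 3.37, SE 0.10, adjusted p = 2.24e-06). IGFBP3, a binding protein of insulin-like growth factors, rose 10.3-fold, from 9.37 ± 0.09 to 12.73 ± 0.03 (log2 fold change 3.37, SE 0.12, adjusted p = 2.73e-06). DUSP6 fell 7.41-fold, from 10.21 ± 0.13 to 7.32 ± 0.11 (log2 fold change -2.89, SE 0.15, adjusted p = 1.8e-05). Here limma called 763 genes higher and 510 lower on drug. Fitting the resistant arrays alone, without the wide spread of the parental pair, gave 2253 and 1685.

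The 12 genes with the largest fitted rise were OLR1 (at least 3.73), TUBA1A (3.83), the placental alkaline phosphatase ALPP (3.77), TAGLN, an actin-binding protein of smooth muscle (3.46), the complement protease C1S (3.45), FN1, IGFBP3, TMEM45A (at least 3.30), STXBP6 (3.24), the nicotinamide methyltransferase NNMT (3.19), the interferon-induced GTPase GBP1 (at least 2.95) and RASGRP1 (at least 2.72). OLR1, GBP1 and RASGRP1 were above background on 0 of the 3 drug-free arrays and TMEM45A on 1. ANO1 fell most (-3.60), followed by the calcium-binding protein CALB1 (-3.11), PLEC (-2.90), DUSP6, CEACAM5 (-2.81), the organic anion transporter SLCO4A1 (-2.75) and the taurine transporter SLC6A6 (-2.59). DCBLD2 (-2.45), the chromatin protein HMGA2 (-2.41), TMEM259 (-2.28), the decoy receptor IL13RA2 (-1.81 or lower, with 0 on-drug arrays above background) and the epithelial factor EHF (-2.12) came next. SLC6A6 lies in the VGLL4 to TOP2B run. The genes that fell had a median of -0.23 on on-drug replicate 3 relative to the other on-drug arrays, and those that rose -0.02. Adjusted p lay between 2.24e-06 and 0.0442. PLEC and TMEM259 lost the call without any 1 of the drug-free arrays or on-drug replicate 2, and EHF also without on-drug replicate 3, with adjusted p up to 0.147 for PLEC; the remaining 21 kept it without any 1 array. PLEC stood at -1.85 without on-drug replicate 3.

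**Figure D2:**
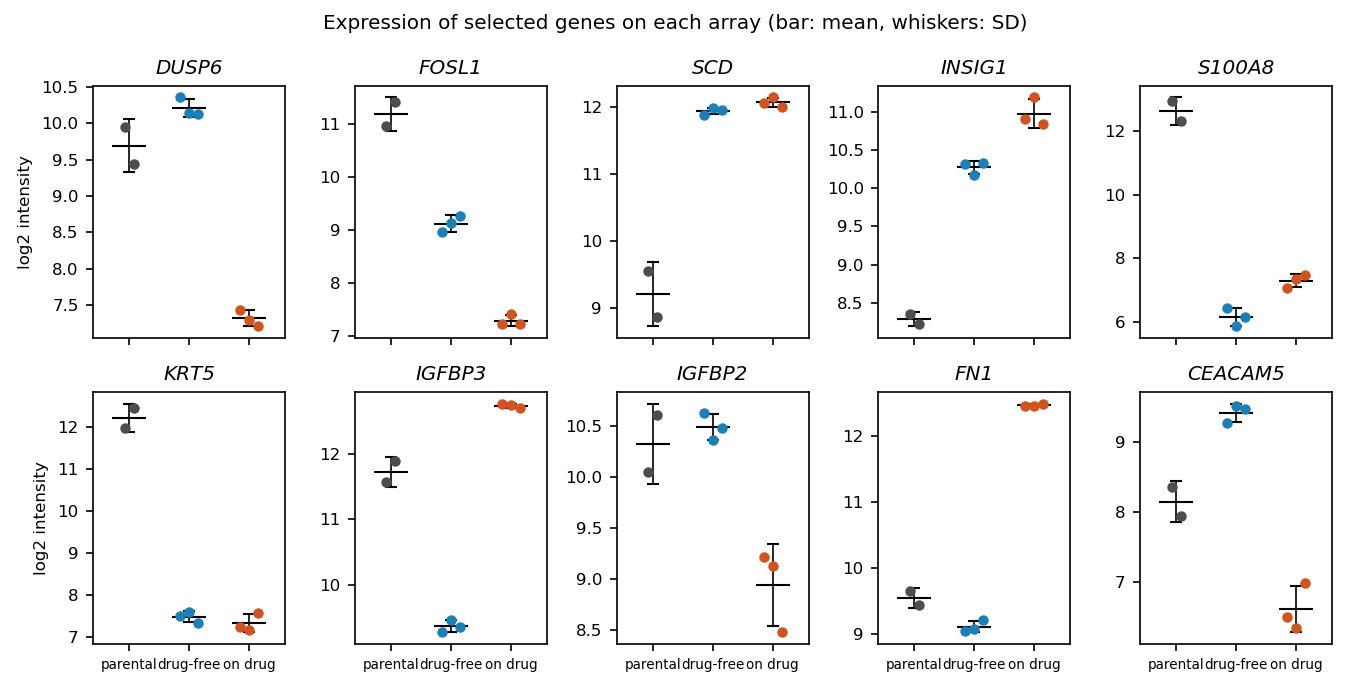
Log2 intensity of DUSP6, FOSL1, SCD, INSIG1, S100A8, KRT5, IGFBP3, IGFBP2, FN1 and CEACAM5 (vertical axis) in parental PC9 (n = 2), drug-free PFR3 (n = 3) and PFR3 on drug (n = 3), with 1 point per array and the mean with its SD. DUSP6 averages 9.69, 10.21 and 7.32, and FN1 9.54, 9.11 and 12.47 in that order of groups.

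Of the ERK pathway output genes, 0 of 18 rose and 15 fell on drug, also when adjusted over the list alone, with a median of -1.21 (camera adjusted p = 5.29e-16; adjusted p = 0.075 with an estimated correlation). DUSP6, the feedback inhibitors SPRY1 (-1.89) and SPRY4 (-1.88) and FOSL1 (-1.84) fell most. Of the DNA replication genes, 12 of 24 fell and 1 rose, or 15 and 1 when adjusted over the list alone (camera adjusted p = 4.49e-08; adjusted p = 0.075 with an estimated correlation). CCNE1 (-1.42), CDT1 (-1.07), MCM5 (-1.02) and MCM7 (-0.89) led. The member that rose, the helicase factor CDC45 (0.73), lies in a run of 25 neighbouring expressed genes, IL17RA to PPIL2, that was higher on drug throughout (median 0.75). In the mitotic list 0 of 25 rose and 5 fell, 7 when adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.623 with an estimated correlation). CCNA2 (-0.80), CDC20 (-0.72), UBE2C (-0.55) and AURKB (-0.49), a cyclin, ubiquitin ligase partners and a kinase of mitosis, fell. On on-drug replicate 3, with its ACTB difference of 1.16, the medians of these 3 lists stood at -0.06, 0.04 and 0.01 relative to the other on-drug arrays. CDT1 lost the call without drug-free replicate 1 or 3 or on-drug replicate 2 (0.0516 to 0.0714), UBE2C without drug-free replicate 2 or 3 (0.0601 and 0.0618), and CCNA2, CDC20 and AURKB without any 1 of the drug-free or on-drug arrays (adjusted p up to 0.17 for AURKB). With the mean of a gene's probe sets CCNA2 stood at -0.53 and was not called.

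In the antigen presentation list 8 of 19 rose on drug and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.678 with an estimated correlation). PSMB9 rose by 1.51, HLA-DMA, which loads class II molecules, by 1.35, PSMB8 by 0.86 and HLA-B by 0.85. Of the YAP and TEAD targets, 3 of 13 rose and 0 fell, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00321; adjusted p = 0.168 with an estimated correlation). They were the matricellular protein CCN1 (2.39), AMOTL2 (1.43) and tissue factor (F3, 0.93). In the epithelial list GRHL2 (0.71) and ELF3 (0.66), both transcription factors, rose, so 2 of 20 rose and 0 fell, or 5 and 0 when adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.572 with an estimated correlation). In the cholesterol synthesis and uptake list INSIG1 rose by 0.70, so 1 of 16 rose and 0 fell, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.491 with an estimated correlation). The interferon response list had 4 of 27 that rose and 0 that fell, or 5 and 0 when adjusted over the list alone (camera adjusted p = 0.0337; adjusted p = 0.678 with an estimated correlation). They were the deISGylase USP18 (1.27), HERC6 (0.83), the interferon-signalling factor IRF9 (0.68) and IFITM1 (0.58). USP18 lies within the IL17RA to PPIL2 run. On on-drug replicate 3 the medians of the antigen, YAP, epithelial, cholesterol and interferon lists stood at -0.04, -0.04, -0.10, -0.12 and 0.00.

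Without on-drug replicate 1 the epithelial, cholesterol and interferon lists had adjusted p = 0.0754, 0.0819 and 0.0751, over ranges of 0.00123 to 0.572, 0.000546 to 0.491 and 0.00835 to 0.678 in all alternatives. The interferon list also lost the call without either parental array (0.12) or drug-free replicate 3 (0.0501), and the cholesterol list after cyclic loess (0.0539) and among genes above the median brightness (0.0533). By fry the antigen presentation list had adjusted p = 0.0593, and the mitotic and interferon lists 0.0941. PSMB8 lost the call without drug-free replicate 2 or 3 or on-drug replicate 1 or 2 (0.0652 to 0.0871), GRHL2 and ELF3 without any drug-free array or on-drug replicate 1 or 2 (0.0508 to 0.181), and INSIG1 without drug-free replicate 2 (0.051). IFITM1 lost it without any drug-free array or on-drug replicate 1 or 3 (0.0558 to 0.112), and IRF9 without drug-free replicate 1 (0.0579).

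With an estimated correlation camera called 0 of the 37 lists between the resistant cultures, 3 had an unadjusted p under 0.05, and fry called 12. The number of lists called by camera fell from 8 to 5 without on-drug replicate 1. The number of genes called was 1273 with all arrays, 3938 without either parental array, 568, 580 and 545 without drug-free replicate 1, 2 and 3, and 746, 597 and 797 without on-drug replicate 1, 2 and 3.

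**Figure D3:**
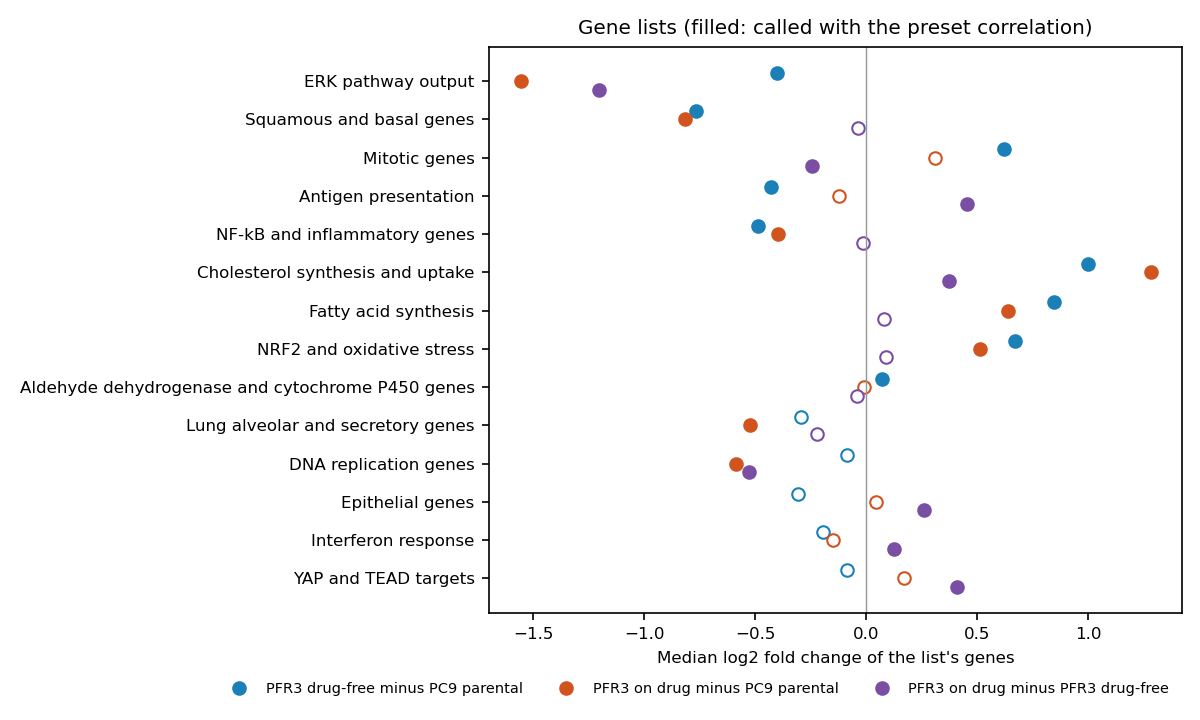
Median log2 fold change (horizontal axis) of the genes of 14 lists in the 3 comparisons, 1 point per list and comparison; filled points were called by camera with its preset correlation and open points were not. The ERK pathway output list stands at -0.40 for drug-free against parental cells, -1.56 for on-drug against parental cells and -1.21 between the resistant cultures.

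In both resistant cultures 963 genes were higher than in parental cells, among them SCD, SLC7A11, CALD1, ACKR3, INSIG1 and HMGCS1, and 816 were lower, among them S100A8, KRT5, KRT13, SPRR1B, LCN2 and FOSL1. Independent lists would share 204 and 211 genes. Simulated groups without effect that share the parental arrays gave means of 262 and 263 with independent noise (at most 312 and 313), and of 626 and 684 with array-wide noise (at most 6661 and 6122), over 100 simulations. The log2 fold changes correlated across genes at 0.83, against simulated means of 0.94 and 0.75, and their covariance was 0.353 against 0.104 and 0.126; genes are not independent replicates. With array-wide noise single simulations reached a correlation of 0.994 and a covariance of 1.22. The parental arrays are too few to be split, and the observed shared counts, correlation and covariance lie within the range of array-wide noise, so part or all of that excess may come from the shared controls. Genes called in opposite directions numbered 41, against 416 for independent lists and a simulated mean of 0.28 with array-wide noise (at most 4). Shared parental arrays push both comparisons the same way, so few such calls can arise without effect. The 41 therefore show no more than that the resistant cultures differ, which their direct comparison tests. Of the shared genes, 279 also differed between the resistant cultures. A further 2922 genes were called against parental cells in the on-drug culture alone, of which 695 also differed between the resistant cultures, and 277 in the drug-free culture alone, of which 98 did. Without drug-free replicate 3 the shared genes numbered 217 higher and 232 lower, and without parental replicate 1 they numbered 2644 and 4357.

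Among the ERBB receptors and ligands, 1 of 11 members fell in drug-free cells and 0 rose, 3 fell on drug against parental cells and 1 fell on drug against drug-free cells, with the same counts when adjusted over the list alone (camera adjusted p = 0.288, 0.294 and 0.451; adjusted p = 0.564, 0.488 and 0.678 with an estimated correlation). Fry, which does not compare a list with the other genes, called this list lower in each comparison (adjusted p = 0.00386, 0.000298 and 0.0223). HBEGF, a ligand of EGFR, fell in each comparison (-0.99, -2.43 and -1.45). EGFR stood at 11.36 ± 0.85, 10.95 ± 0.19 and 10.21 ± 0.16 log2 units in parental, drug-free and on-drug cells. It fell on drug against parental cells (-1.16, SE 0.30, adjusted p = 0.0171), while the drug-free difference (-0.41, adjusted p = 0.327) and the difference between the resistant cultures (-0.74, adjusted p = 0.133) were not called. EGFR lies in a run of 25 neighbouring expressed genes, BLVRA to PSPH, with a median log2 difference of -0.54 between drug-free PFR3 and parental replicate 1. The neuregulin NRG2 is counted among the 3 on drug (adjusted p = 0.034), but 0 arrays of any group were above background, so no change can be read from it. ERBB3 was 0.84 higher on drug than in parental cells without passing the test (adjusted p = 0.051), and ERBB2, ERBB4, EGF, TGFA, EREG, BTC and NRG1 were called in none of the 3 comparisons under the primary settings. For ERBB2 a second probe set gave -1.27 on drug against parental cells, where the brightest gave 0.04.

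Leaving out 1 array changed several of these calls. The fall of EGFR on drug had adjusted p = 0.0543 without on-drug replicate 3, in a range of 8.59e-07 to 0.0719 over all alternatives, and its size was -0.56 without parental replicate 1 and -1.75 without replicate 2. EGFR was called lower in drug-free cells without parental replicate 2 (-1.01, adjusted p = 0.00417, in a range of 9.43e-05 to 0.707), and between the resistant cultures without either parental array (0.00159, in a range of 4.54e-06 to 0.354). ERBB3 was called higher without on-drug replicate 3, drug-free (0.0371) and on drug (0.00307). On drug against parental cells ERBB3 also passed with an intensity trend (0.046), among genes above the median brightness (0.0474), after cyclic loess (0.0481) or median centring (0.0408) and with replicates as a block (0.017), in a range of 1.95e-05 to 0.233. Without parental replicate 2, EREG was called lower drug-free (5.66e-05) and on drug (7.42e-06), with 0 arrays of either resistant culture above background. EGF (-0.56 and -0.56, adjusted p = 0.0251 and 0.0119) and TGFA (-0.64 and -0.64, adjusted p = 0.00372 and 0.00136) were called lower in both resistant cultures without that array as well. Without parental replicate 1, NRG1 was called lower in both (-0.45 and -0.56, adjusted p = 0.00593 and 0.00157), and ERBB2 (-0.27, adjusted p = 0.0415) and NRG2 (0.0359) were called lower in drug-free cells. Over all alternatives adjusted p against parental cells, drug-free and on drug, ranged from 1.45e-07 to 0.827 and 2.57e-08 to 0.213 for EREG, 7e-04 to 0.655 and 0.000125 to 0.625 for EGF, 0.000194 to 0.668 and 6.51e-05 to 0.581 for TGFA, and 0.00593 to 0.883 and 0.00157 to 0.479 for NRG1. NRG2 lost the call without parental replicate 2, any drug-free array or on-drug replicate 1 or 2 (0.0508 to 0.115). ERBB2 stood 0.34 higher on drug than in parental cells when parental replicate 2 and on-drug replicate 3 were both left out. With the mean of a gene's probe sets TGFA was called lower on drug against parental (-0.80) and drug-free cells (-0.42), ERBB2 likewise (-0.61 and -0.62), and EGFR between the resistant cultures (-1.12). Array weights called ERBB3 higher between these cultures by 0.44, and an intensity trend called EREG on drug and NRG2 drug-free lower. Against parental cells array weights lost the calls of HBEGF drug-free (adjusted p = 0.0646) and of EGFR and NRG2 on drug (0.0719 and 0.334).

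In the IGF axis list, 3 of 18 members rose and 3 fell in drug-free against parental cells, 4 rose and 7 fell on drug against parental cells, and 1 rose and 5 fell on drug against drug-free cells. Adjusted over the list alone these were 4 and 4, 4 and 8, and 1 and 5 (camera adjusted p = 0.678, 0.522 and 0.0987; adjusted p = 0.796, 0.808 and 0.623 with an estimated correlation). Fry called the list lower against parental cells, drug-free and on drug (adjusted p = 0.0371 and 0.006), and not between the resistant cultures (0.298). The list's medians against parental cells were -0.13 drug-free and -0.24 on drug, beside -0.13 and -0.11 over all genes. Since fry does not compare a list with the other genes, its drug-free call cannot be told apart from the shift of all genes. IGF1R, the receptor, stood at 8.11 ± 0.33, 8.57 ± 0.05 and 8.80 ± 0.54 log2 units, and its differences of 0.46, 0.68 and 0.23 were not called (adjusted p = 0.251, 0.0803 and 0.686). With parental replicate 2 and on-drug replicate 3 both left out, IGF1R on drug stood 0.75 above parental and 0.53 above drug-free cells. That setting was chosen after the data were seen. IGFBP3 fell by 2.36 in drug-free cells and rose on drug, by 1.01 against parental and 3.37 against drug-free cells; it lies in the BLVRA to PSPH run, as does GRB10, and IGFBP1 lies between its genes. Other binding proteins fell on drug, IGFBP2 with -1.38 against parental and -1.55 against drug-free cells, and IGFBP4 with -0.96 and -1.0. In the same comparisons the adaptor IRS1 (-1.83 and -1.31), the secreted STC2 (-2.40 and -1.62) and the adaptor GRB10 (-0.58 and -0.48) fell, and STC2 also fell by 0.78 in drug-free cells. IRS2 rose against parental cells by 0.87 drug-free and 0.67 on drug, the scavenging receptor IGF2R by 0.49 in both, and IGFBP6 by 0.79 in drug-free cells. The insulin receptor INSR rose by 0.75 on drug against parental cells, IGFBP1 fell drug-free (-0.44) and on drug (-0.42), and IRS4 fell on drug (-0.38). IGF1, IGFALS, IGFBP5, IGFBP7 and PAPPA were called in none of the 3 comparisons under the primary settings, and a second probe set of IGFBP5 gave 3.54 on drug against parental cells where the brightest gave -0.18.

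Of these, IGF1R was called higher on drug than in parental cells without parental replicate 1 (0.0303) or on-drug replicate 3 (0.00883), and IRS1 lower in drug-free cells without parental replicate 2 (0.0228). Without parental replicate 1, IGF1 (-0.48 and -0.53, adjusted p = 0.00372 and 0.0019) and IGFALS (-0.57 and -0.58, adjusted p = 0.00149 and 0.00111) were called lower in both resistant cultures, and in drug-free cells IGFBP5 (-0.41, adjusted p = 0.0427) and IRS4 (0.0242) lower and INSR (0.0203) higher. IGFBP6 was called higher on drug than in parental cells without parental replicate 2 (0.68, adjusted p = 0.0135). In drug-free cells the rise of IGFBP6 was 0.50 without parental replicate 1 and that of IRS2 0.56 without replicate 2. The rise of IRS2 on drug against parental cells was 0.36 without parental replicate 2. Over all alternatives IGF1 reached 0.67 and 0.485, IGFALS 0.858 and 0.817, and IGFBP5 0.808 drug-free. Between the resistant cultures IGFBP6 was called lower (0.0293) and INSR higher (0.0315) without either parental array. Array weights called IGF1R (0.36) and INSR (0.43) higher and IGFBP6 (-0.26), IRS2 (-0.25), IRS4 (-0.20) and PAPPA (-0.17) lower there. Against parental cells they lost the calls of IGF2R, IGFBP1 and IRS2 in both resistant cultures, with adjusted p up to 0.472. They also lost those of IGFBP6 and STC2 drug-free and of INSR, IGFBP2, GRB10 and IRS4 on drug. Cyclic loess lost those of IGFBP1 (adjusted p = 0.0662 drug-free and 0.0818 on drug), IRS2 (0.0501) and IRS4 (0.156), the last 2 on drug. Against parental cells in drug-free PFR3, IGF2R, IGFBP1, IGFBP6 and IRS2 lost the call when 1 array was left out, with adjusted p up to 0.164. For IGF2R this happened without parental replicate 2, any drug-free array or on-drug replicate 1 or 2, for IGFBP1 and IGFBP6 without any drug-free array or on-drug replicate 2, for IGFBP6 also without on-drug replicate 1, and for IRS2 without drug-free replicate 2 or 3. On drug against parental cells, IGF2R and IRS4 lost it without parental replicate 2 or on-drug replicate 1 or 2, IRS4 also without any drug-free array, IRS2 without parental replicate 2 or any on-drug array and IGFBP1 without on-drug replicate 1 (0.0512 to 0.124). GRB10 lost its call between the resistant cultures without any drug-free array or on-drug replicate 1 or 2 (0.069 to 0.122). With the mean of a gene's probe sets IGF2R stood at 0.50 drug-free and 0.055 on drug, INSR at 0.19 on drug and STC2 at -0.33 drug-free against parental cells, and these calls were lost, while IGFBP5 was called higher on drug against parental (0.75) and drug-free cells (0.98).

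Markers of stromal, endothelial and blood cells, which pure cultures should lack, showed 0 of 16 that rose in the 3 comparisons. CDH5, the endothelial cadherin, fell in drug-free (-1.68) and on-drug cells (-1.60) against parental cells, and the monocyte marker CD14 fell by 0.55 on drug. Fry called the list lower against parental cells (adjusted p = 0.0274 drug-free and 0.0162 on drug), and not between the resistant cultures (0.802). The list's medians against parental cells were -0.20 drug-free and -0.32 on drug, beside -0.13 and -0.11 over all genes. Counts were 1, 2 and 0 that fell, also when adjusted over the list alone (camera adjusted p = 0.136, 0.129 and 0.663; adjusted p = 0.637, 0.693 and 0.853 with an estimated correlation).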

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

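The tests of RNA degradation in parental replicate 2, of GC-linked bias between the parental arrays and of scaling between arrays were chosen only after the result was seen.

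For genes called in opposite directions against parental cells, independent lists would give 416 and simulations without effect at most 4. Those simulations share the parental arrays, which push both comparisons the same way, so they set no bar for this count. Observed were 41 such genes, each also called between the resistant cultures. The number was 123 and 68 without parental replicate 1 and 2, 15, 13 and 13 without drug-free replicate 1, 2 and 3, and 23 and 16 without on-drug replicate 1 and 2. Among these 41 genes, the largest differences between the resistant cultures were TUBA1A (3.83), C1S (3.45), FN1 (3.37) and IGFBP3 (3.37), which were lower drug-free and higher on drug than in parental cells. CALB1 (-3.11) and CEACAM5 (-2.81) went the other way. Of the probe sets without a gene name, 551 of 2108 were called between on-drug and parental cells, 170 between drug-free and parental cells and 150 between the resistant cultures. Of the 10 splits of the 6 resistant arrays, 1, the real one, gave as many as 1273 genes and the highest other gave 0; 10 splits are too few for a share under 0.05.

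Parental replicate 2 differed from replicate 1 by more than 1 log2 unit in 1335 genes. RNA degradation in replicate 2 is argued against by the ACTB 3' minus 5' difference, which was -0.018 for replicate 2 minus replicate 1. PFR3 RNA mixed into replicate 1 is argued against only as the sole source of the difference. The 400 genes at least 2 log2 units higher in drug-free PFR3 than in replicate 2 would need a share of 55.5%. The 32 genes as far lower should then have had a median of -0.88 on replicate 1 relative to replicate 2. It was -0.45 (quartiles -0.54 and -0.03), 0.43 above the prediction. Of these 32 genes 25 were lower on replicate 1, the direction a mixture predicts, so a smaller share is not excluded. Both sets were chosen on replicate 2, so a bias of that array would also change the share needed. A GC-linked bias between the parental arrays is a candidate explanation, since bright genes on GC-rich chromosomes had a median of 0.42 for replicate 2 minus replicate 1 and those on GC-poor chromosomes -0.58, a difference of 1.01; over genes of any brightness the medians were 0.37 and 0.016, closer than the 0.4 set for bright genes. A difference between the parental cultures themselves was not tested and stays open.

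ERK pathway output genes were lower on drug than drug-free, with a median of -1.21 over 18 genes. RNA degradation in the on-drug arrays is argued against, since on-drug replicate 3, with the largest ACTB difference, had a median of -0.058 for these genes relative to on-drug replicates 1 and 2 (quartiles -0.15 and 0.18). After cyclic loess the median was -1.21 as well. The values had already been quantile-normalised, so this step could shift it little and does not decide on scaling between arrays. The hypothesis that the drug's presence lowers these genes may hold, but each culture state was sampled in 1 group, and a difference that arose between the cultures during separate growth was not tested.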

How the results depend on the processing

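The omission of parental replicate 2 together with on-drug replicate 3 is the setting chosen only after the result was seen. The 68 sign changes of values called in neither fit are counted here as unchanged. Of the named genes' values under settings that kept all arrays, 1689 kept the main side of the threshold without a called reversal, 105 lost a call, 22 gained 1 and 3 reversed. Under omission of 1 array these were 1711, 155, 30 and 0, and under the joint omission 214, 1, 22 and 0. List shifts kept their call in 135, 189 and 23 cases and lost it in 37, 11 and 2, in the same order. With the mean of a gene's probe sets, ERBB2 on drug against parental cells was -0.61, ERBB2 on drug against drug-free cells -0.62 and IGFBP5 on drug against parental cells 0.75, opposite in sign to the brightest probe set, since the probe sets of both genes disagree.

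In what follows comparisons are drug-free against parental, on drug against parental, and on drug against drug-free, and pairs of counts are genes higher and lower. Genes above the median brightness gave 1360 lower in the second and 463 higher in the third comparison, with fewer genes tested. Every probe set on its own gave 3768 and 4475 in the second and 1271 and 1254 in the third, with more features tested. Array weights, which weighted each parental array 0.109, gave 422 and 132, 1328 and 532, and 3200 and 2772, with 394 and 99 shared by both resistant cultures. Fits of only the groups compared gave 172 and 221, 1387 and 1104, and 2253 and 1685, with 152 and 173 shared; the parental pair's difference is then absent from the spread of the third. A change of at least 1 log2 unit left 553 and 173, 1247 and 496, and 240 and 136. Camera with an estimated correlation called 0, 0 and 0 lists, fry's directional test 23 and 25 in comparisons with parental cells, and fry's mixed test 36, 37 and 32.

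Leaving out arrays gave 235 to 2910 higher and 280 to 5056 lower in the first comparison, 1638 to 5149 lower in the second, and 350 to 2609 higher and 195 to 2173 lower in the third, where the highest come from the joint omission. The highest of the first and second come without parental replicate 1. Shared genes ranged from 217 to 2644 higher and 232 to 4357 lower, and lists called in the third comparison from 5 to 10. Of the 2097, 4742 and 1273 genes called, 1595, 3709 and 1273 were called with the same sign without parental replicate 2, and 2069, 4220 and 1273 in the joint omission, which called 3303, 5635 and 4782. Without either parental array the parental pair's difference leaves the estimate of the spread, which raises the third count; the cause of the other changes was not tested.

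The replicate number as a block gave 546 and 443 genes in the first comparison and 501 and 359 shared. Deviations of same-numbered arrays from their group means correlated at -0.05, 0.14, 0.09, -0.02, 0.09, -0.15 and -0.14, so no shared effect of the replicate number was visible. These values depend on each other, since deviations are taken from group means, and cannot show whether samples were handled in pairs. Share of calls that were higher under cyclic loess was 47.6%, 53.6% and 59.7%, against 51.7%, 47.5% and 59.9%. The upper decile of the bacterial controls was 5.55 log2 units on parental replicate 2 and 5.16 to 5.31 on the other arrays. Their median was 4.66 on parental replicate 2 and 4.41 to 4.55 on the others. Background was thus highest on parental replicate 2, and signal over background was not compared between arrays. Genes at or below the upper decile of an array have only a bound there.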

Other observations

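The tests of GC-linked bias along the runs of genes were chosen only after the result was seen, and so were the runs themselves, the condition on how far dim genes spread and the genes named in the next paragraphs.

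On drug, mesenchymal genes were split: 5 of 21 rose and 2 fell against drug-free cells, also when adjusted over the list alone (camera adjusted p = 0.0501; adjusted p = 0.678 with an estimated correlation). Fry called this list higher (adjusted p = 0.00985). FN1 rose by 3.37 and TAGLN by 3.46, the collagen COL5A1 by 1.5, the transcription factor SNAI2 by 1.0 and vimentin (VIM) by 0.87, while COL6A1 (-0.83) and S100A4 (-0.65) fell. TGF-beta and BMP signalling genes had 4 of 20 that rose and 2 that fell, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.489; adjusted p = 0.678 with an estimated correlation). This list too was called higher by fry (adjusted p = 0.0223). ID3 rose by 2.39, the decoy receptor BAMBI by 1.76, the activin subunit INHBA by 0.99 and LTBP1 by 0.55, while ID1 (-1.59) and SMAD3 (-0.41) fell. Among other receptor tyrosine kinases and ligands 0 of 27 rose and 4 fell, 1 and 4 when adjusted over the list alone (camera adjusted p = 0.478; adjusted p = 0.826 with an estimated correlation), among them the ephrin receptor EPHA2 (-1.45) and the growth factor PDGFA (-0.65). Against parental cells 1 of these 27 rose and 0 fell drug-free, and 3 rose and 8 fell on drug, also when adjusted over the list alone (camera adjusted p = 0.678 and 0.522; adjusted p = 0.825 and 0.836 with an estimated correlation). Fry called these receptors and ligands lower on drug against parental cells (adjusted p = 0.0304), and not in the other comparisons (0.168 drug-free and 0.248 between the resistant cultures). Their median on drug against parental cells was -0.17, beside -0.11 over all genes. The receptor tyrosine kinase AXL rose by 0.97 drug-free and 1.10 on drug, while EPHA2 (-1.88), PDGFA (-1.05) and TYRO3 (-0.97) fell on drug.

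Of the FOXO targets, 7 of 15 rose and 3 fell on drug against parental cells, or 8 and 3 when adjusted over the list alone (camera adjusted p = 0.0738; adjusted p = 0.39 with an estimated correlation). Fry called the list higher there (adjusted p = 0.00166). The cyclin CCNG2 rose by 1.99, the cell cycle inhibitor CDKN1B by 1.91 and the repressor BCL6 by 1.69, while KLF4 (-1.96), KLF2 (-0.53) and GADD45A (-0.32) fell. In the BCL2 family the pro-apoptotic BIK fell in each comparison (-1.84, -2.55 and -0.72). BID, which links death receptors to mitochondria, fell drug-free (-1.11) and rose on drug by 0.65 against parental and 1.77 against drug-free cells, and the protective BCL2L1 fell by 0.53 between the resistant cultures. Of 13 members of this family 2 rose and 2 fell drug-free and 3 rose and 3 fell on drug against parental cells, or 2 and 2 and 3 and 4 when adjusted over the list alone (camera adjusted p = 0.366 and 0.644; adjusted p = 0.679 and 0.886 with an estimated correlation). Between these cultures 1 of 13 rose and 2 fell, or 1 and 3 when adjusted over the list alone, with a median of 0.04, a mean of 0.02 and a camera test in the lower direction (camera adjusted p = 0.663; adjusted p = 0.853 with an estimated correlation). Fry called the BCL2 family lower against parental cells, drug-free and on drug (adjusted p = 0.0244 and 0.0162), and not between the resistant cultures (0.877). Its medians against parental cells were -0.24 drug-free and -0.06 on drug, beside -0.13 and -0.11 over all genes. On drug the family's median thus did not lie below that of all genes. Calls of the genes named in these paragraphs outside the rule were not recomputed with arrays left out.

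Runs of 25 neighbouring expressed genes shifted together: IL17RA to PPIL2, which holds BID and CDC45, had a median of 0.75 on drug against drug-free cells, with 25 of 25 genes higher and 17 called (permutation p = 0.001, the smallest that 1000 shuffles of gene order can give), and VGLL4 to TOP2B and BLVRA to PSPH had 0.98 and -0.54 between drug-free PFR3 and parental replicate 1. Arrays of 1 group gave runs as well, with a median down to -1.42 for parental replicate 2 minus replicate 1 (permutation p = 0.009) and -0.30 for on-drug replicate 3 minus the other on-drug arrays (p = 0.006), so a run alone does not set a difference between cultures apart from 1 between arrays; medians per array of the stretches were computed too and not used as tests, because they ran on the genes chosen for the pattern. A GC-linked bias between arrays is argued against for IL17RA to PPIL2, where GC-rich minus GC-poor chromosomes gave -0.14. A gain of IL17RA to PPIL2 in the on-drug culture, a gain of VGLL4 to TOP2B in PFR3 and a loss of BLVRA to PSPH in PFR3 may lie behind the runs; the dimmer genes of each stretch outside the search had medians of 0.11 (17 genes, 10 on the predicted side), -0.057 (5 genes, 1 on that side) and -0.12 (8 genes, 6 on that side). All 3 cannot be told apart from shared regulation of the stretches. The medians of 0.11 and -0.12 lie between the bounds set in advance. That of -0.057 met the bound set in advance for excluding a gain of VGLL4 to TOP2B. The condition on spread, added after the result was seen, withholds that exclusion. Log2 fold changes between drug-free and parental cells had a median absolute deviation of 0.15 in genes of that brightness, against 0.41 in brighter genes. The 0.41 includes the difference between the parental arrays, so these values do not show that dimmer genes could not respond.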
